A study of Caenorhabditis elegans with 357 samples.

How the data were processed

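Single Caenorhabditis elegans animals in the fourth larval stage (L4) were profiled by polyA RNA sequencing, with 1 library per animal. The labels give each animal a strain and the minutes it had spent in L4 when it was collected. Growth, imaging and lysis are described in the labels' protocols: each animal was raised from an egg in its own arena, imaged, cut with a needle and frozen. The series' design text names SMART-seq2, and the labels' protocols name Nextera tagmentation for the libraries. The alignment tool STAR 2.7.9a is named in the submitters' processing notes. Its settings, the genome build, the annotation and the counting tool are not given in the sources used here, nor is the use of strand in counting, so overlapping and antisense genes and near-identical copies (major sperm proteins, histones, gpd-2 and gpd-3) are uncertain as single genes.

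The deposited values are RPM, the reads of a gene scaled by the reads in all listed genes of its library. This unit was taken from the names of the 2 deposited tables, 1 per strain, and tested on the values. The first data line of each table holds the labelled minutes, which matched the labels for all 357 animals, and was left out of the values. The tables list 19382 genes for N2 and 19379 for tph-1, of which 19364 are in both. Each table lists only genes with a read in at least 1 of its animals. The low values of every library are whole multiples of what 1 read is worth, so whole reads were recovered. In every library 100% of the values came out whole within 0.1 reads. Of the 19397 symbols in either table, 18734 matched the Ensembl 115 annotation of WBcel235, which gave all coordinates and gene identifiers; some unmatched symbols had been turned into dates. Since both tables were divided by their own library totals over nearly the same genes, with at least 99.991% of the reads of every library in the shared genes, the RPM of both strains were tested together.

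The recovered reads in genes ranged from 587469 to 11544404 per animal in N2 (median 2922062) and from 437993 to 5175666 in tph-1 (median 1764815). A single read was therefore worth between 0.0866 and 2.28 RPM, and a gene below that level could not be seen in a single animal. Reads without molecular identifiers are not independent molecules, so depth gives counting error only. No library fell below 60% of the median number of genes at 1 RPM, so leaving out such libraries removed nothing and was not run. No pair of libraries held identical values.

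The number after the strain in each label title splits the animals into 8 N2 sets and 4 tph-1 sets. The labels do not define it; it was treated as a run, and each set holds 1 strain. The labels name each library as a single animal, so animals are separate samples, but animals of 1 set share whatever the set stands for. The comparison of strains was therefore made over the 12 sets, and no set gives a strain difference of its own. The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

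Tests were limma (3.58.1, with trend) on log2(RPM + 1) in R 4.3.3, over the 14293 genes with at least 5 RPM in at least 10% of the animals, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(RPM + 1) scale, which understates the change of low genes. Within each strain, a natural spline of the minutes with 4 degrees of freedom was tested with an F test, with set as a covariate, and a gene was called when its fitted curve also ranged over at least 1 log2 unit between 30 and 570 min. Signed changes came from a fit of early (under 200 min), middle (200 to under 400 min) and late (400 min or later) windows with set as a covariate: late minus early, and middle minus the mean of both ends, called at an absolute change of at least 1. Strain was tested in 2 stages: a shared spline of minutes with an intercept per set, then limma on the 12 intercepts. The interaction of strain with the spline was tested over animals with set intercepts, and its signed size was the tph-1 minus N2 difference of the late against early change. The spread between animals was the SD of residuals around each strain's spline, compared between strains over the 12 sets on the log2 scale. Errors beside log2 changes are standard errors.

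Gene lists, 33 in number, were tested with camera at a preset correlation of 0.01 and with the correlation estimated. A transcriptional age was predicted by partial least squares with 5 components (scikit-learn 1.9.0, Python 3.11.15) from all tested genes, trained on N2 with 1 set left out at a time, and applied to tph-1 from all N2 animals. Its strain offset was the difference of set intercepts at a common slope on the labelled minutes, tested over all 495 splits of the 12 sets into 8 and 4 with an exact two-sided permutation test. Correlations were tested with 100000 permutations, two-sided.

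The named genes are, per comparison, the 6 largest increases and the 6 largest decreases past the threshold at a mean of at least 10 RPM, the 6 smallest p of the unsigned tests (8 genes for the description of spread in N2), up to 4 members with the smallest p of each list, and tph-1 with the rest of the serotonin list. The genes plotted along L4 were picked by hand among named genes. Alternatives covered the pseudocount, the filter, median-of-ratios rescaling, set and recording camera as covariates, the spline's degrees of freedom, the window limits, the weighting of sets, edgeR (4.0.16) on the recovered reads, the settings of the age model and leaving out each set.

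The fits were tested on simulated data with the real sampling times and sets, with 100 genes changed at each fold among the 14293. At 2-fold and 4-fold, late against early recovered 65% and 100% in N2 and 76% and 99% in tph-1. Middle against ends recovered 100% at both folds in both strains. Both window tests were scored at the adjusted p alone, without the threshold on the size of the change that the calls use. Recovery with that size threshold was not measured, so these shares do not give the power of the calls. Strain recovered 89% and 100%, and the interaction 28% and 92%. The spline test, scored without its range threshold, recovered 3% and 61% in N2 and 8% and 82% in tph-1. It thus missed most 2-fold changes even before that threshold. The recovery of 80% at 4-fold that was asked of the other tests was dropped for the spline after this was seen. Between 3 and 19 unchanged genes were called per simulated comparison. Only the strain simulation held differences between sets, drawn apart for each gene, and every simulation used a single fixed dispersion. The recoveries and false calls therefore leave out structure of the real sets and are not error rates for the real animals. A simulated age offset of 25.0 min was recovered as 20.6 min at a slope of 0.969, against a slope of 0.766 in the real animals. That was 1 draw with its own times, sets and genes and no differences between sets. It does not measure a bias of the age model.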

Results

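The data are 357 single-animal transcriptomes of L4 larvae, 193 from N2, the wild-type laboratory strain, and 164 from mutants of tph-1, which encodes the tryptophan hydroxylase of serotonin synthesis. The labelled time in L4 ran from 10.7 to 599.2 min in N2 and from 9.6 to 596.0 min in tph-1. The early, middle and late windows held 49, 67 and 77 N2 animals and 47, 70 and 47 tph-1 animals. A median of 14373 genes reached 1 RPM in N2 and 15334 in tph-1. The mitochondrially encoded transcripts took 3.72% ± 1.66 (SD, n = 193) of the reads in N2 and 2.32% ± 0.77 (SD, n = 164) in tph-1.

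The tph-1 transcript itself (WBGene00006600, chromosome II, 7549335 to 7551983, WBcel235) was low in both strains. Its mean in the early, middle and late windows was 4.93, 3.72 and 3.45 RPM in N2 and 4.66, 2.45 and 1.41 RPM in tph-1 animals. The SDs were 5.32, 3.60 and 3.58 RPM and 4.22, 2.79 and 1.604 RPM. The strain difference was -0.46 ± 0.23 on the log2 scale and did not pass the test (limma adjusted p = 0.192, 4 sets against 8). Under 4 of 28 alternatives it did: over animals without a set term (-0.44), with edgeR over animals (-0.72), and with sets 1 to 4 of each strain, blocked or not (-0.53), with adjusted p from 7.1e-05 to 0.581 over all alternatives. The value is a total over the gene, and the labels do not say which part the allele removes, so it does not check the strain labels. Of the serotonin list with tph-1, the reuptake transporter mod-5 and the receptor ser-1, 0 of 14 members passed limma, over all genes or adjusted over the list alone. Of these, 2 had an unadjusted p under 0.05, mod-5 at 0.44 ± 0.19 and the channel ocr-2 at 0.44 ± 0.20.

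The study's title asks for transcriptional dynamics through development, which the time courses within each strain address. In N2, 7300 of 14293 genes changed along L4, and in tph-1 10702 did; 6765 changed in both. Whether the counts differ between the strains was not tested. The smallest p in N2 belonged to cuticle collagens: col-160 peaked at 30 min and was lowest at 330 min, and col-139, col-129, col-13, col-181 and col-20 peaked at 570 min. In tph-1 the smallest p belonged to dao-2, which peaked at 240 min, sym-1 at 190 min, fkb-5 at 240 min, col-133 at 530 min, noah-2, a component of the apical matrix, at 220 min, and Y39A1A.9 at 140 min. Of the changing genes, 37.8% (2759) peaked in the first 100 min and 25.5% (1863) in the last 100 min in N2. In tph-1 the shares were 62.4% (6676) and 15.4% (1648). These shares are from RPM and were not computed after rescaling, which lowers the tph-1 count as given below. Peaks were sought between 30 and 570 min, so a gene that falls throughout counts as peaking at 30 min. The adjusted p alone, without the range of 1 log2 unit, called 11121 genes in N2 and 13646 in tph-1. Past 1.5 times, the N2 count moved to 4373 with a filter at a mean of 10 RPM, and the tph-1 count moved to 5201 with that filter, 6325 with a pseudocount of 5 and 6087 after rescaling of the libraries.

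**Figure D1:**
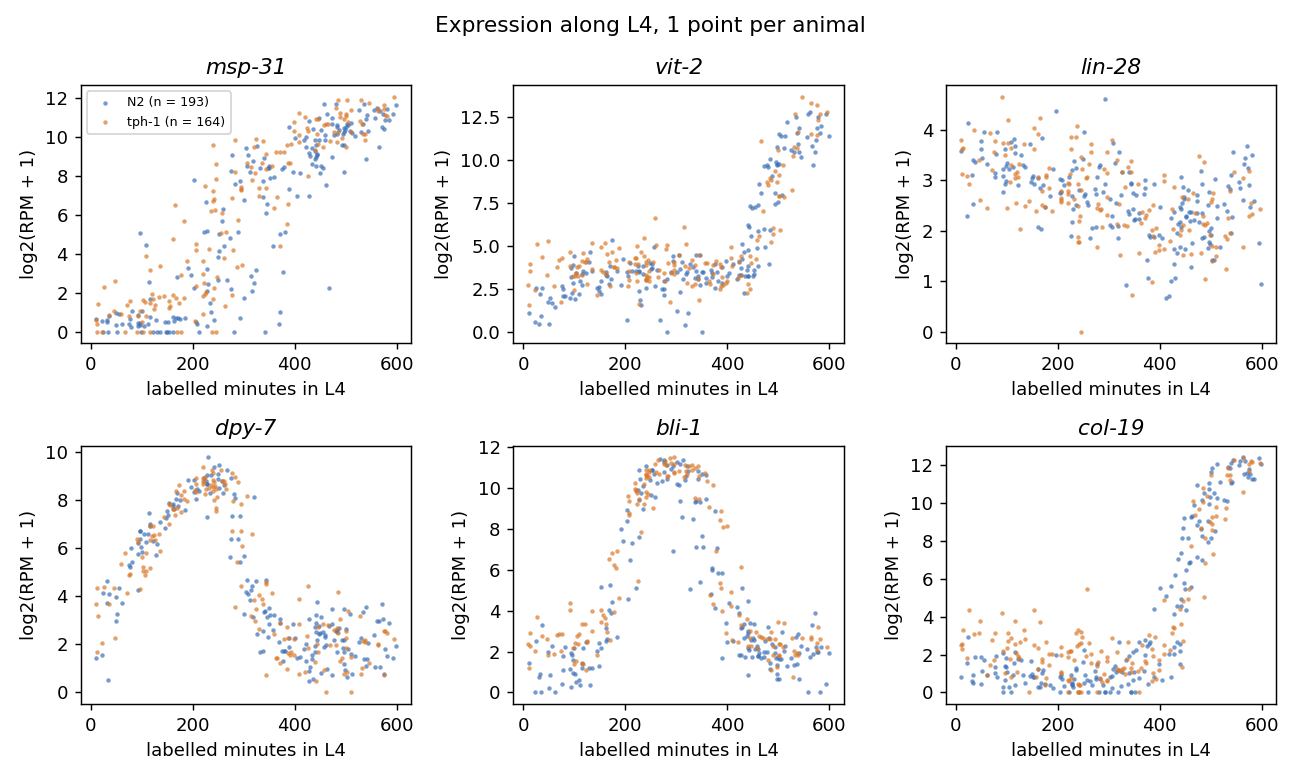
Expression of msp-31, vit-2, lin-28, dpy-7, bli-1 and col-19 along L4, with the labelled minutes on the x axis, log2(RPM + 1) on the y axis and 1 point per animal (N2, n = 193; tph-1, n = 164). In both strains msp-31, vit-2 and col-19 are high late, bli-1 peaks in the middle window and dpy-7 falls before 400 min.

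Late against early, most members of the major sperm protein, vitellogenin, oocyte and sperm lists rose in both strains. Major sperm proteins, the cytoskeletal proteins of nematode sperm, rose in 45 of 46 members in N2 and 45 of 46 in tph-1, with msp-31 up by 7.10 ± 0.63 and msp-3 by 7.10 ± 0.61 in N2 and msp-65 by 7.14 ± 0.44 in tph-1. All 6 vitellogenins, the yolk proteins, rose in N2 and 5 of 6 in tph-1: vit-6 by 4.66 ± 0.60 and 3.86 ± 0.44, and vit-2 by 4.19 ± 0.68 and 4.00 ± 0.50. The oocyte list rose in 17 of 25 members in N2 and 14 of 25 in tph-1, with the eggshell genes perm-2 (5.37 ± 0.38 and 5.38 ± 0.29) and perm-4 (5.11 ± 0.42 and 5.46 ± 0.33). The sperm list rose in 17 of 22 and 13 of 22, with the phosphatases gsp-3 (4.44 ± 0.47 and 3.87 ± 0.29) and gsp-4 (4.32 ± 0.42 and 4.02 ± 0.28). These counts were the same adjusted over the list alone, and major sperm proteins are near-identical copies that are uncertain as single genes. With an estimated correlation, camera's adjusted p was 0.0457 in N2 and 0.0241 in tph-1 for major sperm proteins, 0.234 and 0.258 for vitellogenins, 0.223 and 0.0804 for oocyte genes, and 0.187 and 0.106 for sperm genes.

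Cuticle collagens went both ways: 73 of 157 rose and 15 fell in N2, and 77 rose and 32 fell in tph-1, the same counts adjusted over the list alone. The largest increases in N2 were col-124 (7.84 ± 0.57), col-38 (7.56 ± 0.89), col-129 (7.45 ± 0.54), bli-6 (7.41 ± 0.56) and col-140 (7.33 ± 0.59), beside msp-31. Those in tph-1 were col-120 (8.79 ± 0.58), Y47D7A.15 (8.20 ± 0.54), col-122 (8.15 ± 0.43), col-60 (8.10 ± 0.46), R12E2.14 (8.05 ± 0.76) and col-162 (7.95 ± 0.61). The adult collagen col-19 rose by 6.10 ± 0.64 and 6.19 ± 0.48, from 1.32 to 1407 RPM and from 5.33 to 1318 RPM. The largest decreases in N2 were col-176 (-6.20 ± 0.53), F46F2.3 (-5.74 ± 0.60), col-98 (-5.72 ± 0.66), pqn-31 and C53B7.3 (both at -5.59) and fipr-1 (-5.57 ± 0.48). Those in tph-1 were col-98 (-8.33 ± 0.61), F46F2.3 (-8.28 ± 0.55), col-176 (-8.14 ± 0.51), grd-3 (-6.76 ± 0.48), C53B7.3 (-6.74 ± 0.41) and fipr-2 (-6.63 ± 0.42). For the cuticle collagens camera's adjusted p with an estimated correlation was 0.0646 in N2 and 0.0271 in tph-1. For the 4 adult cuticle genes, of which 3 rose in N2 and 2 in tph-1, it was 0.0457 and 0.0804. One of the 3 is bli-1, at 1.28 in N2, whose mean went from 12.97 to 4.85 RPM; its call was kept in 10 alternatives, lost in 6, among them without N2 sets 1, 2, 6, 7 or 8 (1.08, 1.09, 1.21, 1.00 and 1.09), and turned to -0.18 with edgeR.

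Members of the lists for larval timing, pharynx, seam and neurons fell in part, and none of these lists passed camera with an estimated correlation. Heterochronic genes, which time larval cell fates, fell in 7 of 17 members in N2 and 12 of 17 in tph-1: dre-1 by -1.55 ± 0.20 and -1.89 ± 0.17, and daf-12 by -1.23 ± 0.16 in N2. The transcription factor myrf-1 fell by 3.35 in N2 and 3.67 in tph-1 (SE 0.21 and 0.17), and blmp-1 by -1.38 ± 0.19 and -1.82 ± 0.16. Pharynx genes fell in 12 of 15 and 9 of 15, with marg-1 at -3.08 ± 0.40 and -3.64 ± 0.30 and the pharyngeal troponin tnc-2 at -2.27 ± 0.36 and -3.31 ± 0.27. Seam and hypodermis genes fell in 7 of 15 and 10 of 15, with grd-10 at -3.82 ± 0.41 and -6.18 ± 0.38, and 1 rose in N2. Neuropeptides fell in 29 of 95 and 44 of 95 (nlp-26 at -2.37 ± 0.30 and -2.73 ± 0.23) and rose in 4 and 5 (ins-37 at 2.81 ± 0.29 and 2.33 ± 0.21). Pan-neuronal genes fell in 3 of 18 and 10 of 18, and serotonin genes in 2 of 14 and 6 of 14, with cat-4, which makes the hydroxylase cofactor, at -1.82 ± 0.28 and -2.55 ± 0.20. With an estimated correlation camera's adjusted p in N2 and tph-1 was 0.517 and 0.582 for heterochronic genes, 0.634 and 0.602 for pharynx, 0.725 and 0.628 for seam, 0.725 and 0.639 for neuropeptides, 0.634 and 0.582 for pan-neuronal genes and 0.81 and 0.708 for serotonin genes. Furrow collagens fell in 6 of 6 members in tph-1 (0.708 with an estimated correlation), while in N2 2 of 6 fell and 1 rose, with a median of -0.69 although camera's direction was up.

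Over all tested genes, 1627 were higher and 1171 lower late in N2, and 1449 higher and 3377 lower in tph-1. The median gene fell by 0.36 in N2 and 0.68 in tph-1; rescaling moved the median by 0.37 and 0.54, and then gave 1937 higher and 521 lower in N2 and 1970 and 882 in tph-1. Of 2454 genes called in both strains, 2447 went the same way, 1371 up and 1076 down, where independent lists would share 165 and 277; across genes, which are not independent replicates, the changes had r = 0.945 and rho = 0.795. In N2 early and late animals occur together in 4 of 8 sets, sets 1, 3, 4 and 5, which hold 1, 2, 2 and 1 late animals; the other sets enter through the middle window. The lower genes in N2 numbered 1873 without N2 set 5. For 19 called N2 genes, dpy-8 and wrt-2 among them, the fitted sign was opposite to the plain difference of the windows' mean log2(RPM + 1), against 0 in tph-1. Lower genes numbered 3793 in N2 without the set covariate and 6022 in tph-1 with edgeR.

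**Figure D2:**
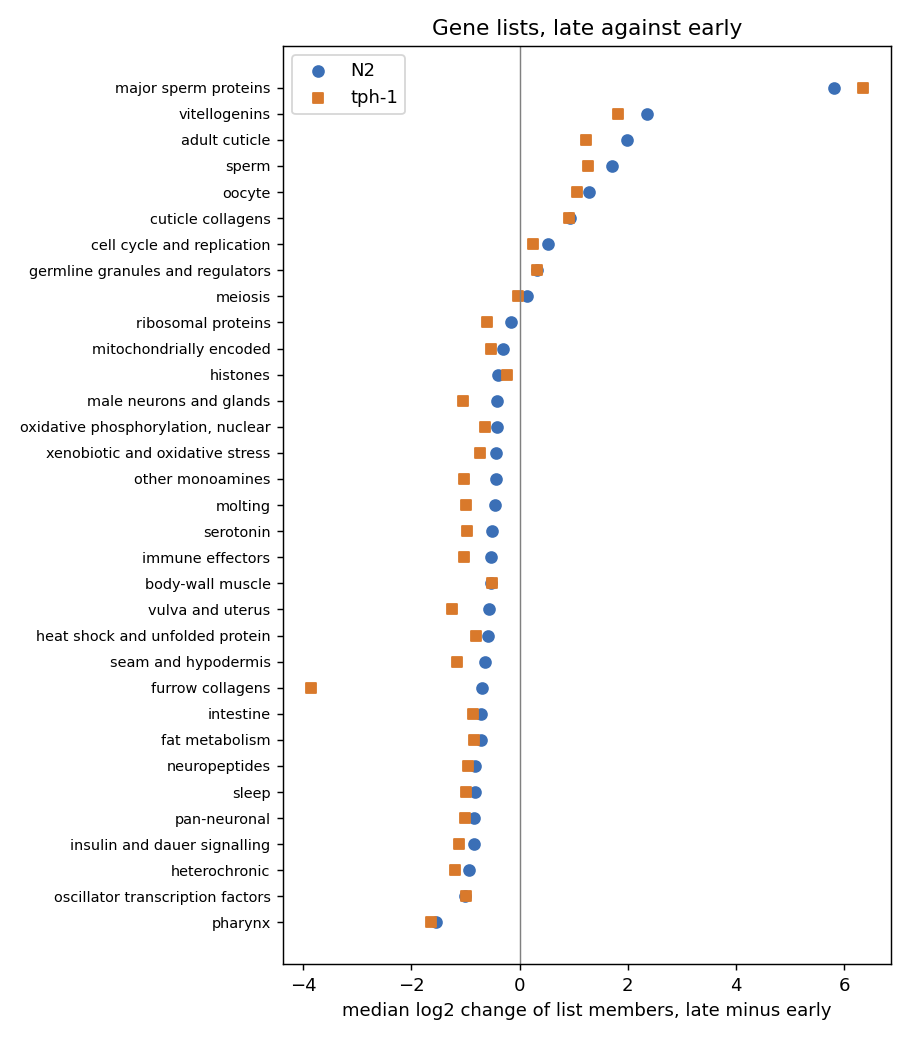
Median log2 change from the early to the late window of the tested members of each of the 33 gene lists (x axis, log2(RPM + 1) scale) in N2 (circles) and tph-1 (squares). Major sperm proteins stand highest, at 5.82 in N2 and 6.35 in tph-1, and furrow collagens lie at -0.69 and -3.86; rescaling turns the sign for ribosomal and mitochondrially encoded genes in both strains, for oxidative phosphorylation in N2 and for body-wall muscle, histones and meiosis in tph-1.

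The middle window was compared with the mean of the early and late windows. There 502 genes were higher and 432 lower in N2, and 435 and 364 in tph-1. By fitted values alone, a count chosen after they were seen and not a test, 488 of the higher and 352 of the lower genes lay beyond both ends in N2, and 399 and 229 in tph-1. The others, such as vit-6 among the lower genes, lay between the early and late windows. The adult cuticle collagens bli-1 (chromosome II, 10708960 to 10712156, WBcel235) and bli-2 were higher by 6.43 ± 0.29 and 7.17 ± 0.36 in N2 and by 6.40 ± 0.26 and 6.89 ± 0.29 in tph-1; bli-1 went from 12.97 to 1003 and back to 4.85 RPM in N2. The collagens lon-3 (6.05 ± 0.36), sqt-1 (6.02 ± 0.49) and rol-8 (5.98 ± 0.46) and the gene Y102A11A.5 (5.80 ± 0.37) rose with them in N2, and lon-3 (5.80 ± 0.31), Y102A11A.5 (6.51 ± 0.38), grl-15 (5.67 ± 0.40) and sqt-1 (5.65 ± 0.40) in tph-1. Lower in the middle were col-160 (-6.51 ± 0.32 and -6.26 ± 0.28), col-93 (-6.28 ± 0.27 and -6.48 ± 0.28), col-159 (-5.91 ± 0.30 and -6.02 ± 0.32) and col-145 (-5.63 ± 0.30 and -6.10 ± 0.29). All 6 furrow collagens, which shape the annular furrows, rose in both strains, with dpy-8 at 3.93 ± 0.37 and 4.32 ± 0.42. Without tph-1 set 1 the lower genes in tph-1 numbered 571.

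Molting genes rose in 12 of 23 members in each strain and fell in 2 in N2 and 1 in tph-1, with mlt-9 at 4.78 ± 0.24 and 4.74 ± 0.22, qua-1 at 4.45 ± 0.27 and 4.40 ± 0.23, mlt-10 at 4.66 ± 0.33 and 3.99 ± 0.31 and the protease nas-37 at 3.06 ± 0.21 and 3.24 ± 0.21. Histones rose in 6 of 21 in N2 and 5 of 21 in tph-1, such as his-18 at 1.38 ± 0.13 and 1.26 ± 0.13. The period homolog lin-42 rose by 1.86 ± 0.15 and 1.85 ± 0.14. With an estimated correlation camera's adjusted p was 0.0181 in N2 and 0.0105 in tph-1 for each of the adult cuticle, molting and histone lists, and 0.286 and 0.216 for furrow collagens. The adult cuticle list went both ways, with bli-1 and bli-2 higher and col-19 (-3.53 ± 0.36 in N2 and -3.08 ± 0.31 in tph-1) and col-7 (-1.53 ± 0.39 and -1.36 ± 0.30) lower than the mean of both ends, which their late rise lifts. Cuticle collagens were higher in 40 and lower in 66 of 157 members in N2, and in 37 and 69 in tph-1. Adjusted over the list alone the numbers were 41 and 66, and 38 and 69, with an adjusted p = 0.505 and 0.233 with an estimated correlation. A pseudocount of 5 gave 254 lower genes in N2 and 229 in tph-1, beyond 1.5 times the main counts.

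Between the strains, at the same labelled minute, 41 genes were higher and 21 lower in tph-1 (limma over 4 sets against 8). The stearoyl-CoA desaturase fat-7 (WBGene00001399, chromosome V, 7151353 to 7153146, WBcel235) was higher by 4.24 ± 0.37, with window means of 1.91, 1.67 and 0.844 RPM in N2 and 68.0, 94.0 and 41.5 RPM in tph-1. The related desaturase fat-6 was higher by 1.49 ± 0.27. Of the fat metabolism list 2 of 33 members were higher and 1 lower, and 4 and 10 adjusted over the list alone, with a median of -0.23 that turns to 0.04 on rescaling. Adjusted over the list alone, 7 of 19 xenobiotic and 3 of 16 heat shock genes were lower, with 0 of each over all genes by limma (8 and 7 at an unadjusted p under 0.05). The adjusted p with an estimated correlation was 0.814, 0.322 and 0.299. The xenobiotic and heat shock counts are from RPM and were not made after rescaling, which moved the median gene of this comparison by 0.23. Other large increases were T01D3.6 (2.87 ± 0.22), the C-type lectin clec-47 (2.87 ± 0.36), C32H11.4 (1.78 ± 0.25), the ABC transporter pgp-6 (1.72 ± 0.33) and dod-24 (1.65 ± 0.25). Lower genes were pgph-2 (-1.32 ± 0.26), F59A7.2 (-1.12 ± 0.22), F48D6.4 (-1.11 ± 0.17), the acyl-CoA synthetase acs-2 (-1.03 ± 0.20), hmit-1.2 (-0.99 ± 0.21) and dhs-20 (-0.90 ± 0.16). In all, 3937 genes had an unadjusted p under 0.05.

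The largest strain differences included the left end of chromosome III. There H10E21.4 (17318 to 19675, WBcel235) had a mean of 0.0011 RPM in N2, with a read in 1 of 193 animals, and 184 RPM in tph-1, with 154 of 164 animals above 0; its fitted difference of 4.82 ± 0.66 depends on the pseudocount. Its neighbours fbxa-6 (0.0024 and 10.6 RPM), npr-30 (0.0013 and 8.98 RPM) and H10E21.5 (0.211 and 11.4 RPM, with reads in 66 of 193 N2 animals) were called likewise. The fatty acid metabolism regulator nhr-80 (11985 to 14869), at 28.5 RPM ± 13.1 (SD, n = 164) in tph-1, and H10E21.1, which overlaps H10E21.4, at 4.14 RPM ± 2.96 (SD, n = 164), have no read in any N2 animal and were not tested. The next genes, from clp-10 at 35454, had reads in both strains, with pck-1 at 81.8 and 78.3 RPM.

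**Figure D3:**
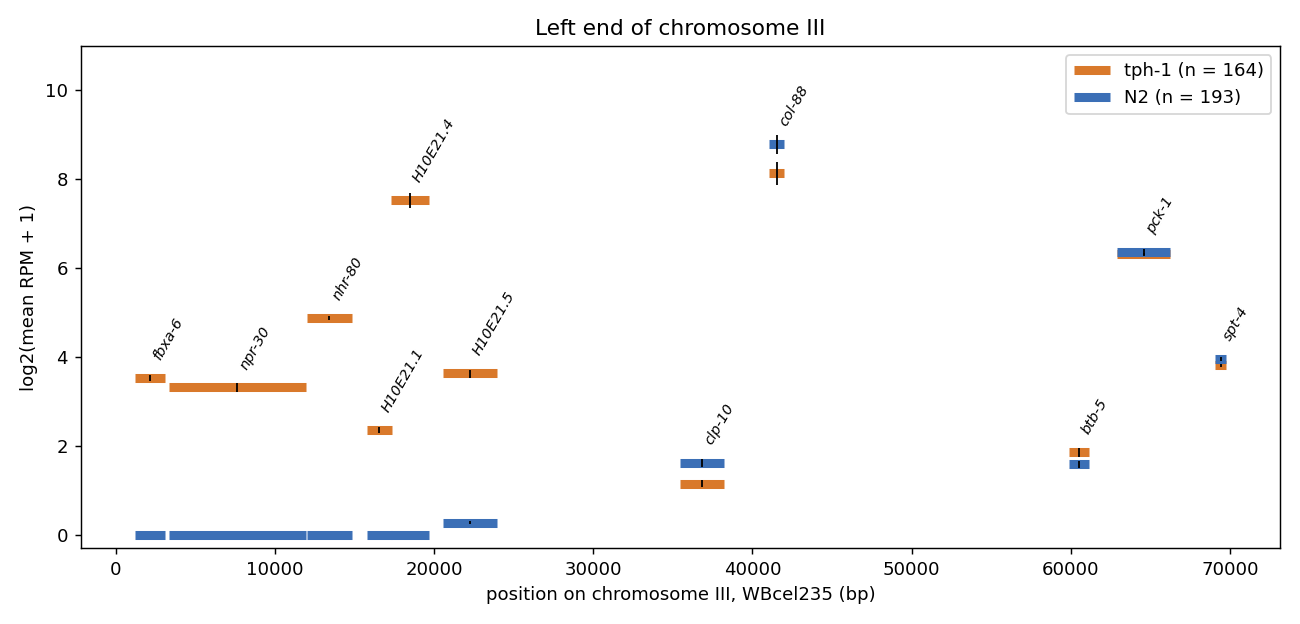
Mean expression of the protein-coding genes at the left end of chromosome III, with the position in WBcel235 on the x axis and log2(mean RPM + 1) on the y axis, horizontal bars spanning each gene and vertical lines the SE over 193 N2 and 164 tph-1 animals. The 6 genes that end by 23962 are at or near 0 in N2, with the highest at 0.211 RPM, and between 4.14 and 184 RPM in tph-1.

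Cuticle collagens were higher in tph-1 in 12 of 157 members, 46 adjusted over the list alone, with a median of 0.38: col-43 by 1.35 ± 0.19, dpy-4 by 1.37 ± 0.21, col-85 by 1.10 ± 0.16, bli-1 by 0.85 ± 0.18 and bli-2 by 0.83 ± 0.16. With transcriptional age in place of minutes dpy-4 (-0.24), bli-1 (-0.0616) and bli-2 (-0.24) turned sign. That age was predicted from all tested genes, these collagens included, so it can take up part of their own difference. The calls of dpy-4, bli-1 and bli-2 were kept in 27, 16 and 19 alternatives and lost in 1, 12 and 9 others. The antimicrobial peptide gene nlp-33 was higher by 0.93 ± 0.17. Of the major sperm proteins 0 of 46 passed limma over all genes and 36 adjusted over the list alone (median 0.77; 37 at an unadjusted p under 0.05). Of the mitochondrially encoded genes 0 of 12 passed over all genes and 12 were lower adjusted over the list alone (median -0.66; 12 at an unadjusted p under 0.05). Their mean share of the reads was 6.45% in N2 set 3, against 2.74% to 4.28% in the other N2 sets and 2.03% to 2.51% in the tph-1 sets. N2 sets 6, 7 and 8, at 3.15%, 2.94% and 2.74%, lay nearer the tph-1 sets than N2 sets 1 to 5, at 3.76% or more. These shares are not adjusted for the minutes. Some recording cameras occur in N2 sets 6 to 8 and in tph-1 sets but not in N2 sets 1 to 5. A gap of this kind thus also occurs between N2 sets, and its source was not tested. With an estimated correlation camera's adjusted p was 0.299 for collagens, 0.322 for major sperm proteins and 0.322 for mitochondrially encoded genes. Rescaling moved the median gene from -0.10 by 0.23 and gave 76 higher and 4 lower genes. Transcriptional age from all tested genes in place of minutes gave 17 and 3. Camera of recording as a covariate gave 19 and 9, and weighting sets by animals 242 and 260. Leaving out N2 set 7 gave 544 higher and 1008 lower genes, N2 set 8 gave 150 and 921, tph-1 set 1 gave 22 and 3 and tph-1 set 3 gave 20 and 2. The lower genes numbered 11 without N2 set 1 or 2, 6 without tph-1 set 2 and 10 without tph-1 set 4.

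The time course itself was compared between the strains. The interaction of strain and time passed in 310 genes, but 53 of 100 splits of the sets gave as many, so this count does not stand out from those of other splits. The smallest p belonged to H10E21.4, F33H12.7, pgp-6, ZK632.4, tba-7 and hpd-1, a dioxygenase of tyrosine breakdown; for H10E21.4, with a read in 1 of 193 N2 animals, the test sets the tph-1 time course against values at 0. The late against early change was more negative in tph-1 in 201 genes and more positive in 5; after rescaling the numbers were 13 and 4. Ribosomal proteins made up 37 of the 201, of 80 tested (72 adjusted over the list alone), such as rpl-25.1 at -0.56 ± 0.11 and rpl-11.2 at -0.68 ± 0.14. Camera's adjusted p with an estimated correlation was 0.206. The ribosomal counts are from RPM and were not made after rescaling, which left 13 more negative genes in all. The desaturase fat-5 had a difference of 1.42 ± 0.40, with a late against early change of -1.67 ± 0.34 in N2 and -0.25 ± 0.21 in tph-1. Furrow collagens were more negative in 2 of 6 members, dpy-8 (-3.69 ± 0.94) and dpy-2 (-3.49 ± 1.02), and in 6 of 6 adjusted over the list alone, with an adjusted p = 0.206 with an estimated correlation. The call was kept in 12 and lost in 9 alternatives for dpy-8 (-4.86 to -0.73), and kept in 6 and lost in 15 for dpy-2 (-4.70 to -0.03). The N2 change of dpy-8 has the opposite sign of its window means, and early and late N2 animals occur together in 4 of 8 sets, the others being joined through the middle window. Leaving out 1 set moved the 310 to 199 (N2 set 5), 697 (tph-1 set 3) or 485 (tph-1 set 4), and the 201 to 356, 53, 439, 7, 91, 56 and 3 (N2 sets 1, 2, 4, 5, 6, 7 and 8) or 56, 18 and 461 (tph-1 sets 1, 3 and 4). The 5 moved to between 1 (N2 set 5 or 8) and 35 (N2 set 4), beyond 1.5 times for every set but N2 set 7 and tph-1 set 2.

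The series' title names the detection of age from behavior; the transcriptome of each animal was compared here with its labelled minute by predicting it. The median absolute error was 31.8 min in N2 animals of sets left out of training and 55.7 min in tph-1. Predicted and labelled minutes had r = 0.943 and rho = 0.947 in N2 and r = 0.962 and rho = 0.969 in tph-1 (permutation p = 1e-05 for each, the smallest 100000 permutations can give; adjusted p = 1.4e-05 for r and 1.6e-05 for rho over 14 groups and sets), and r = 0.945 and 0.961 without the 2 animals farthest from the median. Within sets r ranged from 0.668 to 0.977; in N2 sets 1, 2 and 6 it fell to 0.445, 0.0195 and 0.307 without the 2 farthest animals, so r in those sets rests on them. There rho over all animals was 0.424, 0.280 and 0.537 (permutation, adjusted p = 0.0868, 0.352 and 0.0185).

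With a common slope on the labelled minutes, tph-1 animals were predicted 50.3 min older than N2 animals (exact permutation p = 0.0242 of 495 splits of 12 sets). Set offsets were 44.98 ± 16.09 min (SD, n = 4) against -5.30 ± 38.4 min (SD, n = 8). Each N2 set was predicted without its own animals, while all tph-1 sets came from a single model of all N2 animals. The 12 offsets are therefore not interchangeable, and the p counts every split but is not exact as a test of strain. Only training on both strains, given next, leaves out every set alike. The call was lost when the model was trained on both strains (19.3 min, exact p = 0.305), with 3 components (41.8 min, exact p = 0.0707) and after rescaling (45.9 min, exact p = 0.0788). It was also lost without N2 set 1 (40.8 min, exact p = 0.0697), N2 set 5 (43.5 min, exact p = 0.0545), tph-1 set 1 (42.7 min, exact p = 0.0848) or tph-1 set 2 (50.3 min, exact p = 0.0667). The offset is a single shift for all of L4. The plain mean of predicted minus labelled minutes differed less between the strains in the late than in the early window. Whether the slope differs between the strains was not tested, so the offset is not that of any given minute.

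**Figure D4:**
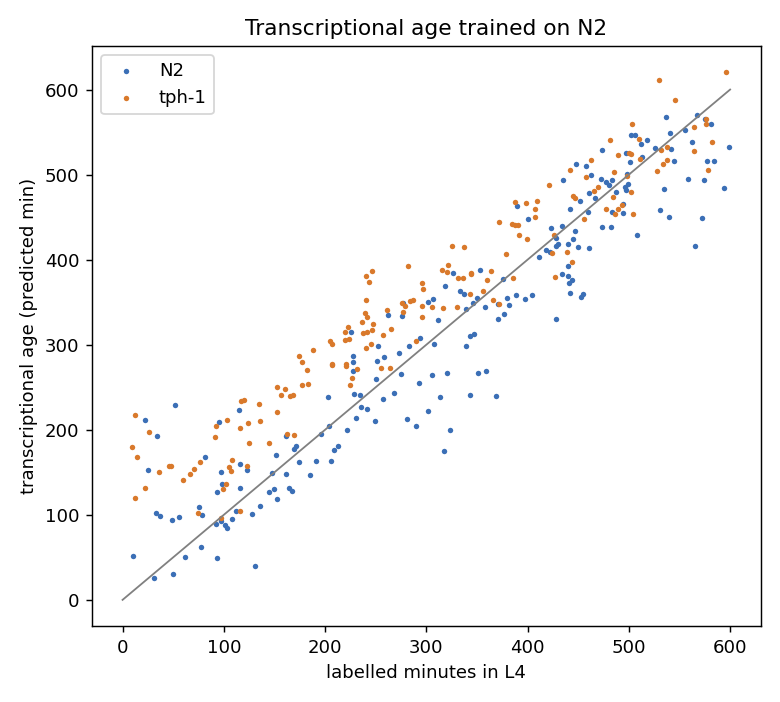
Transcriptional age in predicted minutes (y axis) against the labelled minutes in L4 (x axis), 1 point per animal, for a model trained on N2, with the line of equality in grey. The median absolute error was 31.8 min in N2 (n = 193) and 55.7 min in tph-1 (n = 164).

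The spread between animals at the same labelled time was similar in size in both strains, with a median residual SD of 0.677 in N2 and 0.702 in tph-1 on the log2 scale. It was higher in tph-1 for 3 genes, npr-30, H10E21.4 and fbxa-6, all of the left end of chromosome III where N2 is near 0, and lower for 0 genes by limma, with 1208 genes at an unadjusted p under 0.05. Within N2, transcripts with the most spread for their level were tag-10, col-73, F01D5.5, dao-4, abu-14, msp-31, col-38 and msp-59. Major sperm proteins and cuticle collagens had medians of 1.05 and 0.56 above the trend of residual SD on level, at the percentile of 100 among 10000 random lists matched on level. Immune effectors and molting genes, at 0.36 and 0.39, were at that percentile too, adult cuticle genes were at 0.73 and percentile 99.98, and many other lists stood high, while nuclear oxidative phosphorylation genes were lowest, at -0.28 and percentile 0. The random lists were matched on level but not on the size of the change along L4. Misfit of the spline for steep genes is therefore not separated from spread between animals. Random lists also do not carry the correlation of near-identical copies. A pseudocount of 5 gave 9 genes with higher spread in tph-1, and a filter at a mean of 10 RPM gave 1.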

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

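The tests of the missing chromosome end, of the gene sets of both tables, of read composition, all fits on thinned libraries or on transcriptional age, the correlation of nhr-80 with fat-6, and the measures of sets searched for values far from the others were chosen after the results were seen.

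The first pattern is that fat-7 and fat-6 were higher in tph-1 while a block of 6 genes at the left end of chromosome III was near 0 in N2; nhr-80, at 28.5 RPM in tph-1, and H10E21.1, at 4.14 RPM, drew attention because only the tph-1 table lists them. Different gene sets of the tables argue poorly for the block, since 0 other genes at 5 RPM or more are listed in a single table and reads of 4 block genes occur in some N2 animals. The block's highest N2 mean was 0.2105 RPM and the next genes had reads in both strains, which is consistent with N2 animals of this study lacking that end; whether this is a deletion in their N2 stock was not tested, since the tables hold no sequence. NHR-80 is a known regulator of fat-6 and fat-7, so their difference may follow the block rather than serotonin, a hypothesis that strain confounds; within tph-1 the residual correlation of nhr-80 with fat-7 was at percentile 42.4 of genes of like level (r = 0.0845, rho = 0.111, permutation p = 0.283 and 0.157, n = 164, r = 0.129 without the 2 farthest animals; r from -0.146 to 0.475 in the 4 sets). That met the bound set beforehand against it, while fat-6 was at percentile 98.5 (r = 0.319), beyond that bound; a correlation where every animal has the gene does not test its absence, so loss of nhr-80 and loss of serotonin cannot be told apart for fat-7.

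The second pattern is that cuticle collagens were higher in tph-1 at the same minute, with a median of 0.38. Depth alone argues poorly for it: with all libraries thinned to the smallest total the median was 0.433 and 13 collagens were called, against 12. A shift in developmental timing may hold part of it: with transcriptional age, trained without collagens, major sperm proteins and called genes, in place of minutes, the median was 0.253 with quartiles of -0.30 and 0.69, and 2 collagens were called, while fat-7 stayed at 4.32. That median lies above the bound of 0.192 set beforehand against timing, but by less than the SE between sets of 0.233, a spread that was added to the rule after the value was seen, so timing and strain cannot be told apart here. A biological difference between the strains stays open and untested.

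The third pattern is the set of genes with an interaction of strain and time, 310 in number, with late against early changes mostly more negative in tph-1; single genes that drew attention because the difference itself passed were dpy-8 (-3.69), lpr-6 (-3.17), sym-1 (-3.06), col-149 (-4.19), lpr-5 (-3.52), dpy-2 (-3.49), H10E21.4 (5.26, with N2 near 0), C32H11.4 (1.75) and fat-5 (1.42). Grouping of the sets by chance is not excluded: 53 of 100 splits of the 12 sets gave 310 or more, with a median of 330 and a highest of 2398. Splits that divide the tph-1 sets unevenly carry part of any strain by time difference. Their counts therefore cannot be credited to structure among the sets alone. Depth argues poorly as the cause of the direction, since 97.6% of the genes called in thinned libraries were more negative in tph-1 (80 of 82; exact interval 91.5 to 99.7). Read composition may account for it: after rescaling 13 of 17 called genes, 76.5%, were more negative, above the bound of 75% that was set after the counts were seen, but with an exact interval of 50.1 to 93.2 that treats genes as independent, so composition and strain cannot be told apart for these genes.

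For the other counts, chance was tested by reordering the minutes within sets or by splitting the 12 sets into 8 and 4, with the real value included among 100. For each time course 1 of 100 orders, the real one, gave as many genes, the smallest share that 100 orders can give. This argues against no link with the minutes in any gene, and does not vouch for the size of the counts. The highest other orders gave 1547 genes against 7300 along L4 in N2 and 383 against 10702 in tph-1. They gave 68 against 2798 and 1 against 4826 late against early, and 75 against 934 and 1 against 799 in the middle. For strain 2 of 100 splits gave 62 genes or more, the real one and N2 sets 1, 4, 5 and 6 against the rest, which gave 82. Splits that mix the strains carry any strain difference as spread within their groups, which lowers their counts. These splits therefore cannot exclude chance for strain. For spread 6 of 100 splits gave 3 genes or more, with a highest of 258, so chance is not excluded.

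The mean share of mitochondrially encoded reads in N2 set 3, 6.45%, stood apart from the other 7 N2 sets by Dixon's test (ratio 0.585). In all 8 groups of set values were searched this way. Chance passes the bound in about 1 in 20 for each group, so a flag somewhere among the 8 is more likely than that.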

How the results depend on the processing

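The settings with thinned libraries, transcriptional age in place of minutes, a slope of 1, animals of 160 to 430 min for the age offset, and sets 1 to 4 without a block were chosen after seeing the data. Transcriptional age in this section was predicted from all tested genes, the collagens included. The cause was not tested for any change given here, except that a stricter filter tests fewer genes. Of the values that answer a comparison, 256 kept their direction and their side of the threshold, or stayed within 1.5 times, 101 counts moved further and 8 values lost their call. Depth limits low genes, since 1 read was worth up to 2.28 RPM.

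Late against early, lower genes in N2 numbered 1865 with a pseudocount of 0.1, 598 with 5, 521 rescaled, 3793 without the set covariate and 684 with windows at 150 and 450 min; higher genes numbered 990 with the filter at a mean of 10 RPM. In tph-1 lower genes numbered 1175 with a pseudocount of 5, 1684 with the filter, 882 rescaled and 6022 with edgeR, and higher genes 941 with the filter. Along L4 the filter gave 4373 genes in N2 and 5201 in tph-1, and tph-1 had 6325 with a pseudocount of 5 and 6087 rescaled. Lower genes in the middle window numbered 254 in N2 and 229 in tph-1 with a pseudocount of 5.

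For strain, higher and lower genes numbered 76 and 4 rescaled, 19 and 9 with recording camera, 242 and 260 with sets weighted, 368 and 3127 with set as a random block, 2866 and 6237 over animals without a set term, 2303 and 6478 with edgeR over animals without a set term, 90 and 66 at 160 to 430 min, and 17 and 3 with transcriptional age. Lower genes alone moved to 13 with a pseudocount of 0.1, 10 without a filter, 33 with the filter and 12 with 3 degrees of freedom. The sets' shared numbers do not pair the samples: same-number correlations of set deviations were 0.166, -0.043, 0.008 and 0.042. With sets 1 to 4 of each strain and the number as a block 1094 and 3972 genes passed, and 756 and 3061 without the block. The blocked age offset was 63.6 min, with an exact p of 0.125, the smallest 4 pairs can give.

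The interaction numbered 176 with a pseudocount of 0.1, 544 with 5, 5264 without the set covariate, 949 with recording camera and 133 thinned. Its more positive and more negative genes numbered 12 and 314 with a pseudocount of 5, 1849 and 2032 without the set covariate, 2 and 80 thinned and 8 and 788 with edgeR, and the more negative 101 with a pseudocount of 0.1 and 13 rescaled. Genes with higher spread numbered 9 with a pseudocount of 5 and 1 with the filter. Lists past camera fell with an estimated correlation from 10 to 0 for the interaction, 17 to 2 late against early in N2, 19 to 2 in tph-1, 11 to 3 in the middle in N2, 14 to 3 in tph-1 and 12 to 0 for strain. The age offset lost its call at 41.8 min with 3 components, 45.9 min rescaled and 19.3 min trained on both strains.

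Single genes turned sign as follows: late against early in N2, dpy-8 to -0.78 without the set covariate and -1.39 with edgeR, dpy-9 to 1.13 and dpy-7 to 0.87 with windows at 150 and 450 min, and bli-1 to -0.18 with edgeR; in the interaction, sym-1 to 0.16 and gpd-2 to 0.0072 without the set covariate; for strain with transcriptional age, bli-2 to -0.24, bli-1 to -0.0616 and dpy-4 to -0.24.

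Leaving out each set in turn gave 6811 to 7863 genes along L4 in N2 and 9730 to 11070 in tph-1. Late against early gave 1562 to 1681 higher and 987 to 1873 (without N2 set 5) lower in N2, and 1327 to 1499 and 2912 to 4618 in tph-1. The middle window gave 480 to 531 and 409 to 497 in N2, and 397 to 493 and 312 to 571 (without tph-1 set 1) in tph-1. Strain gave 20 (tph-1 set 3) to 544 (N2 set 7) higher and 2 (tph-1 set 3) to 1008 (N2 set 7) lower, the interaction 199 (N2 set 5) to 697 (tph-1 set 3), with 1 (N2 set 5) to 35 (N2 set 4) more positive and 3 (N2 set 8) to 461 (tph-1 set 4) more negative. Spread gave 3 to 4 higher and 0 lower, and the age offset 40.8 to 58.6 min.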

Other observations

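The tests of nhr-80 with fat-5 and fat-6 were chosen after their values were seen.

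Members of other lists also changed late against early, although none of the lists in this paragraph passed camera with an estimated correlation. Fat metabolism genes fell in 9 of 33 members in N2 and 15 of 33 in tph-1, with the desaturases fat-4 (-1.17 ± 0.16 and -1.73 ± 0.13) and fat-2 (-1.03 ± 0.18 and -1.24 ± 0.11) and the elongase elo-2 (-1.66 ± 0.24 and -2.20 ± 0.17). Insulin and dauer signalling genes fell in 8 of 26 and 14 of 26, among them the glycolytic gene gpd-2 (-1.13 ± 0.10 and -1.77 ± 0.09) and daf-9, which makes the steroid hormone of dauer control (-1.97 ± 0.23 and -2.48 ± 0.21). Immune effectors fell in 7 of 20 and 10 of 20 and rose in 2 in each strain. Oscillator transcription factors fell in 5 of 11 in each strain, vulva and uterus genes in 2 of 17 and 9 of 17, sleep genes in 6 of 14 and 7 of 14, intestine genes in 5 of 18 and 7 of 18, and heat shock genes in 4 of 16 and 7 of 16. Heat shock genes rose in 1 member in each strain, and insulin and dauer signalling genes in 1 in N2. Cell cycle genes rose in 3 of 28 and fell in 1 in each strain, with the cyclin cyb-1 at 2.75 ± 0.33 and 3.18 ± 0.20. With an estimated correlation camera's adjusted p in N2 and tph-1 was 0.634 and 0.582 for fat metabolism, 0.517 and 0.582 for insulin and dauer signalling, 0.921 and 0.816 for immune effectors, and 0.634 and 0.508 for cell cycle. It was 0.634 and 0.582 for oscillator transcription factors and for sleep, 0.654 and 0.628 for vulva and uterus, 0.739 and 0.639 for intestine, and 0.654 and 0.65 for heat shock.

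Further lists were compared late against early, and none of them passed camera with an estimated correlation. In N2 and tph-1, other monoamine genes fell by limma in 0 of 15 and 9 of 15, male neuron and gland genes in 0 of 9 and 5 of 9, xenobiotic and oxidative stress genes in 2 of 19 and 4 of 19, body-wall muscle genes in 1 of 17 and 2 of 17, and molting genes in 8 of 23 and 11 of 23. Germline granule genes rose in 1 of 24 in N2 and 0 of 24 in tph-1 and fell in 2 of 24 in each strain, and meiosis genes rose in 1 of 27 in each strain. Nuclear oxidative phosphorylation genes fell in 0 of 23 and 2 of 23, ribosomal proteins in 0 of 80 and 2 of 80, mitochondrially encoded genes in 0 of 12 in each strain, and histones in 2 of 21 and 3 of 21. Molting genes rose in 4 and 3 members, histones and ribosomal proteins in 1 each in each strain, and other monoamine genes in 1 in N2. At an unadjusted p under 0.05 and any size, lower other monoamine genes numbered 4 in N2 and 12 in tph-1. Male neuron and gland genes numbered 2 and 9, and oxidative phosphorylation genes 23 and 23. Lower ribosomal proteins numbered 26 and 78, and mitochondrially encoded genes 4 and 10. Higher ones were 2 ribosomal proteins in each strain, and 2 other monoamine genes in N2 and 1 in tph-1. These counts are from RPM and were not made after rescaling. Whether they differ between the strains was tested through the interaction alone.

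Within tph-1 animals the residual of nhr-80 correlated with that of fat-6 at r = 0.319 and rho = 0.356 (permutation p = 3.0e-05 and 2.0e-05; adjusted p = 9.0e-05 and 6.0e-05 over 3 genes), and r = 0.336 without the 2 farthest animals, at percentile 98.5 of genes of like level. For fat-5 the values were r = 0.185 and rho = 0.159 (permutation p = 0.0178 and 0.0431; adjusted p = 0.0267 and 0.0647), at percentile 84.5. The permutations allow for no variation that genes share across animals, while the percentiles compare with other genes. These p therefore overstate how unusual both correlations are, and the percentiles are the better guide.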
